A study of Mus musculus with 2 samples.

How the data were processed

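The material was mouse leukaemia cells carrying the MLL-AF9 fusion and Cas9, a DNA-cutting nuclease that is directed by a single guide RNA (sgRNA). Per the labels, 1 library came from cells with an sgRNA against the part of Jmjd1c that encodes the Jumonji domain, and 1 library came from cells with an sgRNA against Renilla luciferase, a sequence absent from the mouse genome that serves as a control. Both cultures were kept with interleukin-3 (IL-3), per the labels' protocols. The libraries are called the Jumonji library and the Renilla library here. No replicate library of either kind was analysed here.

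The deposited values are raw counts of unique molecular identifiers (UMIs, short tags that mark single RNA molecules) per gene and cell barcode. Per the labels' protocols the libraries were made with the 10x Genomics Chromium 3′ kit, version 2 chemistry, which reads the 3′ end of polyadenylated RNA. Per the submitters' processing notes, Cell Ranger 1.3.1 and the mouse build mm10 were used. The annotation release and the rule by which barcodes were called as cells are not given in the sources used here. The deposited matrices held 651 barcodes for the Renilla library and 652 for the Jumonji library, with 27998 gene identifiers. Of these identifiers, 27645 were found in GENCODE M21, an annotation on the same genome build, which supplied the coordinates given below (1-based). A symbol shared by several identifiers occurred 65 times, and such genes were kept apart by identifier.

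Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. This left 608 Renilla and 575 Jumonji cells. Every excluded barcode was excluded by its mitochondrial share, and none had fewer than 500 genes. Scrublet, a doublet caller, marked 10 Renilla cells (1.64%) and 4 Jumonji cells (0.696%). These cells were kept, and leaving them out was an alternative.

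Because each condition had 1 library, cells were not treated as replicates and no test between conditions was made. UMIs were summed over the kept cells of a library and divided by its total to give CPM, the count scaled to the same library total. The log2 ratio of CPM, Jumonji over Renilla, is given with the exact 95% interval of a ratio of Poisson counts, from the conditional binomial distribution. Sums carry exact Poisson intervals and shares of cells carry exact Clopper-Pearson intervals. All of these intervals cover counting error only. They say nothing of the spread between cultures, guides or library preparations. Where a gene had 0 UMIs in 1 library, the ratio was computed against a floor of 3 counts in that library. Over all cells it is then a lower bound. The same floor was used within clusters, some of which hold few cells of 1 library. There it can pull a ratio toward or past 0. Ear6, with 0 Renilla UMIs, had a log2 ratio of -0.30 in cluster 5. Signs within clusters and means over clusters carry this limit.

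Genes were listed as higher or lower by size alone, with at least 100 UMIs over both libraries and a ratio of at least 2 either way. Genes were named by a rule fixed before the data were examined. The rule took Jmjd1c, Kdm3a, Kdm3b and the IL-3 receptor family, the 12 higher and 12 lower genes whose interval bound nearest to 0 was largest, and, for each list described, the 2 highest and 2 lowest members with at least 50 UMIs plus members at least 2-fold apart. Gene lists (33, with 602 different genes) were also fixed before the data were examined. For each list the median log2 ratio of members with at least 50 UMIs was placed among the medians of 10000 random lists of the same size, matched on expression in 20 bins. The percentile describes these 2 libraries and is no test of the guide's effect.

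Cells were clustered jointly with scanpy 1.11.5 and leidenalg 0.10.2 (counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, resolution 0.6). To let cluster sizes be compared, 5556 genes were left out of the clustering: those at least 1.5-fold apart between the library sums, the S and G2/M lists, and mitochondrial and ribosomal protein genes. Cell type names were to be given only from markers of 9 types fixed beforehand. No cluster had 3 of a type's markers among its leading genes, so the 7 clusters are referred to by number. Cell cycle phases were called from S and G2/M scores after each cell was thinned at random to 10000 UMIs. This left out 29 Renilla and 55 Jumonji cells below that depth.

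The ratio, its interval and the random-list percentile were tested on simulated data with the libraries' own sizes and gene means. In the simulated comparison of the Jumonji with the Renilla library, 8922 genes passed the count minimum and 194 of 200 genes changed by 3-fold passed the 2-fold size rule. No unchanged gene did, and 95.4% of intervals held the true ratio. A first check used a single list of unchanged genes, which fell at percentile 98.9, outside the central 95%. Calibration was therefore judged over 200 lists of unchanged genes instead, of which 192 fell inside that range and 106 lay above percentile 50. The simulation draws Poisson counts and genes that vary independently, so it checks the arithmetic and not the spread between real libraries.

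Alternatives were other scalings (median ratio, and TMM from edgeR 4.0.16 in R 4.3.3), the mean of per-cell CPM, all barcodes, a stricter cell filter (at least 1000 genes and at most 5% mitochondrial UMIs), cells without doublets, cells thinned to 1 depth, other count minimums, other clustering settings, and a mean over clusters. Leaving out cluster 6 was added after the clusters had been seen. The stricter filter and the cells without doublets were thinned anew for the phase calls, and scores were recomputed each time. The same filters on the first thinning draw, and another draw of all kept cells, were therefore added after the phases had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, with matplotlib 3.10.9 for plots.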

Results

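JMJD1C is a member of the JmjC family of histone demethylases, enzymes that remove methyl groups from histone lysines. The comparison asked how the transcriptome of MLL-AF9 leukaemia cells differs when the Jumonji domain of JMJD1C is targeted by Cas9. MLL-AF9 is a fusion oncoprotein that drives acute myeloid leukaemia, and these mouse cells grew with IL-3, a cytokine that myeloid progenitors depend on. Single-cell UMI counts were taken from 1 Renilla control library and 1 Jumonji library, so no difference given here has a replicate check. The Renilla library held 14418743 UMIs in 608 kept cells, with a median of 23528 UMIs (quartiles 18942 and 28520) and 4328 genes per cell. The Jumonji library held 12809661 UMIs in 575 kept cells, with a median of 22123 UMIs (quartiles 15035 and 27790) and 4164 genes. The median mitochondrial share was 3.43% in the Renilla library and 2.64% in the Jumonji library.

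Jmjd1c itself (chromosome 10, 67096125 to 67256326, plus strand, mm10) was 1.25-fold lower in the Jumonji library. It had 1435 UMIs there, or 112 CPM (106 to 118), against 2025 UMIs, or 140 CPM (134 to 147), in the Renilla library. The log2 ratio was -0.33 (95% counting interval -0.42 to -0.23), and it was below 0 in each of the 7 clusters. Counts of 3′ ends give a gene's level and not its sequence, and the position of the guide was not examined, so this level does not check whether the gene was edited. The paralogue Kdm3b had a log2 ratio of -0.32 (-0.57 to -0.08), while Kdm3a, at -0.06 (-0.40 to 0.28), differed by less than its counting interval. The 3 measured members of this list had a median of -0.32, at percentile 13.2 of random lists, or -0.05 as a mean over clusters. Kdm3b was lower in 4 of 7 clusters, and Hr was below the count minimum. Among 15 measured histone lysine demethylases the median was -0.09, at percentile 47.1. Kdm7a was higher at 1.22 (0.89 to 1.56) and Phf2 was lower at -0.65 (-0.99 to -0.32).

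Transcripts of the IL-3 receptor family stood higher in the Jumonji library, the beta chains more than the alpha chains. Receptor protein was not measured. Csf2rb (chromosome 15, 78325752 to 78353847), the beta chain shared by the IL-3, IL-5 and GM-CSF receptors, was at 117 CPM against 35.2 CPM, a ratio of 3.32 (3.0 to 3.68). Its neighbour Csf2rb2 (chromosome 15, 78282507 to 78305721), the mouse beta chain specific to IL-3, was at 20.2 against 4.85 CPM, a ratio of 4.16 (3.19 to 5.50). Both were higher in each of the 7 clusters. The alpha chains differed less, with log2 ratios of 0.39 (0.24 to 0.55) for Il3ra and 0.48 (0.36 to 0.60) for Csf2ra. Csf2ra encodes the alpha chain of the GM-CSF receptor. It was above 0 in each of the 7 clusters, but only at 0.02, 0.08, 0.13 and 0.04 in clusters 1, 4, 5 and 6. Il3ra was higher in 6 of 7 clusters and lower in cluster 1, at -1.11. Over the 4 measured members the median was 1.10, at percentile 99.97 of random lists. Csf2rb and Csf2rb2 are near-identical copies, so the split of UMIs between them is uncertain. Il5ra had 2 UMIs against 1, too few for a comparison.

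Signalling genes linked to this receptor differed from list to list. Of 20 measured JAK-STAT targets and components, 6 were at least 1.5-fold higher in the Jumonji library and none was that much lower. The median was 0.34, at percentile 99.96. Cish, a feedback inhibitor induced by STAT5, was higher at 1.58 (1.41 to 1.75), Osm at 1.48 (1.03 to 1.94) and Id2 at 2.44 (1.75 to 3.19), while Stat5a was lower at -0.45 (-0.78 to -0.13) and Id1 at -0.41 (-0.51 to -0.31). Of 10 measured RAS-MAPK response genes, 3 were at least 1.5-fold higher, among them Dusp1 at 1.10 (0.46 to 1.77) and Phlda1 at 1.49 (0.62 to 2.43), but the median was 0.01, at percentile 67.0. The other 14 genes of that list were below the count minimum. The 21 measured RAS-MAPK components had a median of -0.03, at percentile 60.9, with 4 higher and 2 lower. Rasgrp4, a RAS activator of myeloid cells, was higher at 1.70 (1.45 to 1.96), Mapk3 (ERK1) at 1.07 (0.91 to 1.23) and Rras at 1.94 (1.14 to 2.81). Hras was lower at -0.90 (-1.26 to -0.55) and Sos2 at -0.66 (-0.95 to -0.37).

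**Figure D1:**
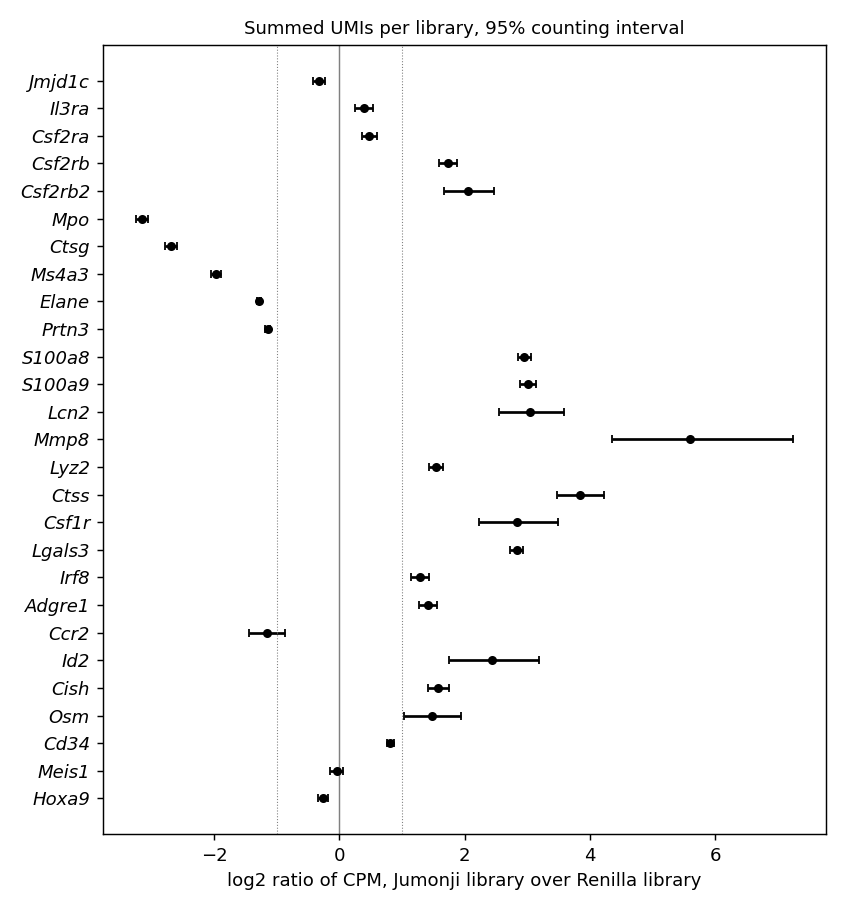
Log2 ratio of CPM, Jumonji library over Renilla library, for 27 genes, with bars for the 95% counting interval of summed UMIs and dotted lines at a 2-fold difference. The IL-3 receptor beta chains, S100a8, Ctss and Lgals3 lie to the right, and Mpo, at -3.15, lies farthest to the left of the genes plotted.

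Genes of primary (azurophil) granules, which promyelocytes make, were lower in the Jumonji library. Mpo (myeloperoxidase, chromosome 11, 87793581 to 87804413) was at 68.4 CPM against 607 CPM, 8.88-fold lower, with a log2 ratio of -3.15 (-3.25 to -3.05). Ctsg (cathepsin G) followed at -2.68 (-2.78 to -2.59), Ms4a3 at -1.97 (-2.04 to -1.89), Elane (neutrophil elastase) at -1.28 (-1.31 to -1.24) and Prtn3 (proteinase 3) at -1.15 (-1.18 to -1.11). All 5 had log2 ratios below 0 in each of the 7 clusters. In cluster 7, which held 11 Jumonji cells, Ms4a3 at -0.003, Elane at -0.07 and Prtn3 at -0.14 differed little. Of the 12 genes of the list, 7 were at least 1.5-fold lower and none was that much higher. Serpinb1a, an inhibitor of neutrophil proteases, went the other way by less, at 0.48 (0.43 to 0.53). The list median of -0.93 lay below all 10000 random lists, and as a mean over clusters it was -0.57.

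Genes of later neutrophil and monocyte stages stood higher. Of 15 measured secondary granule and neutrophil genes, 11 were at least 1.5-fold higher and 1, Camp at -1.76 (-2.18 to -1.36), was lower, though within clusters it was lower in 2 of 4 with enough counts. The median of 1.54 lay above all random lists. S100a8 and S100a9, which form the inflammatory protein calprotectin, were at 498 against 64.3 CPM and at 337 against 41.8 CPM. Lcn2 was higher at 3.05 (2.55 to 3.59), Mmp8 at 5.60 (4.35 to 7.23), or 4.43 without cluster 6, and Lyz2 at 1.54 (1.43 to 1.65). Of 14 measured monocyte and macrophage genes, 9 were higher and 2 lower by 1.5-fold, and the median of 1.10 again lay above all random lists. Ctss (cathepsin S) was higher at 3.84 (3.47 to 4.23), or 3.14 without cluster 6, Csf1r, the receptor for macrophage colony-stimulating factor, at 2.83 (2.23 to 3.48) and Lgals3 at 2.83 (2.72 to 2.94). Ccr2 was lower at -1.15 (-1.44 to -0.87), or -1.94 without cluster 6, and Apoe at -0.94 (-1.59 to -0.31). Averaged over clusters with equal weight, the neutrophil median was 1.04 and the monocyte median 0.59, both below the values over all cells. The floor used within clusters may account for part of this, and its share was not measured.

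Markers of other myeloid lineages were measured at lower counts. All 5 measured eosinophil genes were at least 1.5-fold higher in the Jumonji library (median 1.81, percentile 99.94, or 0.98 in thinned cells, 1.03 at a minimum of 200 UMIs and 1.08 as a mean over clusters), with Prg2 at 2.54 (2.08 to 3.04), or 1.52 without cluster 6, and Siglecf at 1.81 (1.18 to 2.48). Ear6 had 60 UMIs against 0, at least 22.5-fold higher against the floor of 3 counts. The lower limit of its counting interval was 17.8-fold. UMIs of this ribonuclease family may be split among near-identical copies. The 4 measured dendritic and MHC class II genes were all higher (median 0.82, percentile 99.6, or 0.56 without cluster 6 and 1.28 at a minimum of 1 UMI). These were Cd74, H2-DMa, H2-DMb1 and Cst3. The rest of the 17 listed genes were below the count minimum, among them H2-Aa, H2-Ab1, H2-Eb1, Ciita and Itgax. Cd74 had 106 UMIs against 3, a ratio of 39.8 (13.2 to 196), and in the Jumonji library it was at 62.3 CPM in cluster 6 and 1.15 CPM in the other cells. Without cluster 6 its log2 ratio went from 5.31 to 3.02. The 6 mast cell and basophil genes had a median of -0.24 (percentile 16.5), with Mcpt8 lower at -2.81 (-4.00 to -1.80) and Ccl9 higher at 1.74 (1.48 to 2.01), or 0.59 without cluster 6. This median turned to 0.13 with all deposited barcodes and to 0.07 at a minimum of 1 UMI, so the list has no stable direction. Pf4, a platelet factor, was higher at 3.86 (2.98 to 4.90) within a megakaryocyte list of 3 measured genes (median 0.80, percentile 96.0), whose median was 3.61 in thinned cells, 0.21 at a minimum of 1 UMI and -0.14 as a mean over clusters. The 3 measured erythroid genes had a median of 0.03 (percentile 61.3). The stromal list had 2 measured genes, with Pecam1 at 1.04 (0.51 to 1.59) and Pdgfrb at 0.26 (-0.07 to 0.59), and no lymphoid gene reached the count minimum.

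The leukaemia programme differed little beside these genes. Among 22 measured genes of the MLL-AF9 programme none was 1.5-fold higher and 2 were lower, Gfi1 at -0.94 (-1.20 to -0.69) and Cdk6 at -0.65 (-0.72 to -0.59). The median of -0.14 lay at percentile 10.2. Hoxa9 and Meis1, members of this list, had log2 ratios of -0.26 (-0.34 to -0.18) and -0.04 (-0.15 to 0.06). Both were picked outside the naming rule after their values had been seen. The 11 measured stem and progenitor markers had a median of -0.11 (percentile 34.2), with Cd34 higher at 0.81 (0.76 to 0.87) and Cd27 lower at -0.71 (-0.96 to -0.46). The log2 ratio of this list's summed CPM was 0.34, of the opposite sign to its median, with Cd34 alone at 586 of the 1140 CPM in the Jumonji library.

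Over all 8959 genes with at least 100 UMIs, 417 (4.65%) were at least 2-fold higher in the Jumonji library and 133 (1.48%) at least 2-fold lower. A difference of at least 4-fold was seen for 129 higher and 6 lower genes, and 7364 genes lay within 1.5-fold. The median log2 ratio of these genes was -0.06. The 12 higher genes whose interval lay farthest from 0 were Lilrb4a at 5.55 (4.96 to 6.22), Lilr4b at 5.81 (4.44 to 7.70), Wfdc17 at 4.64 (4.41 to 4.87), Mmp8, Serpina1b at 5.58 (4.34 to 7.22), Lilra6 at 4.72 (4.12 to 5.39), Cd200r4 at 4.68 (4.01 to 5.45), Pira2 at 4.37 (3.99 to 4.78), Gm14548 at 4.88 (3.93 to 6.02), Serpina3g at 4.14 (3.84 to 4.46), Nov at 4.21 (3.83 to 4.60) and Dhrs3 at 5.38 (3.8 to 7.68). Lilrb4a, Lilr4b, Lilra6 and Pira2 belong to a family of paired immunoglobulin-like receptors of myeloid cells. Members of this family, of Serpina1 and of Serpina3 are close copies, so single members are uncertain. The 12 lower genes chosen in the same way were Mpo, Ctsg, Ms4a3 and Camp, given above, and Chchd10 at -2.22 (-2.43 to -2.01), Cgnl1 at -2.08 (-2.42 to -1.76), Slc28a2 at -2.57 (-3.54 to -1.72), Gm43194 at -2.28 (-3.12 to -1.53), Matk at -1.60 (-1.82 to -1.38), Ppic at -1.61 (-1.88 to -1.34), Bag2 at -1.66 (-1.99 to -1.34) and AY036118 at -1.51 (-1.72 to -1.30).

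**Figure D2:**
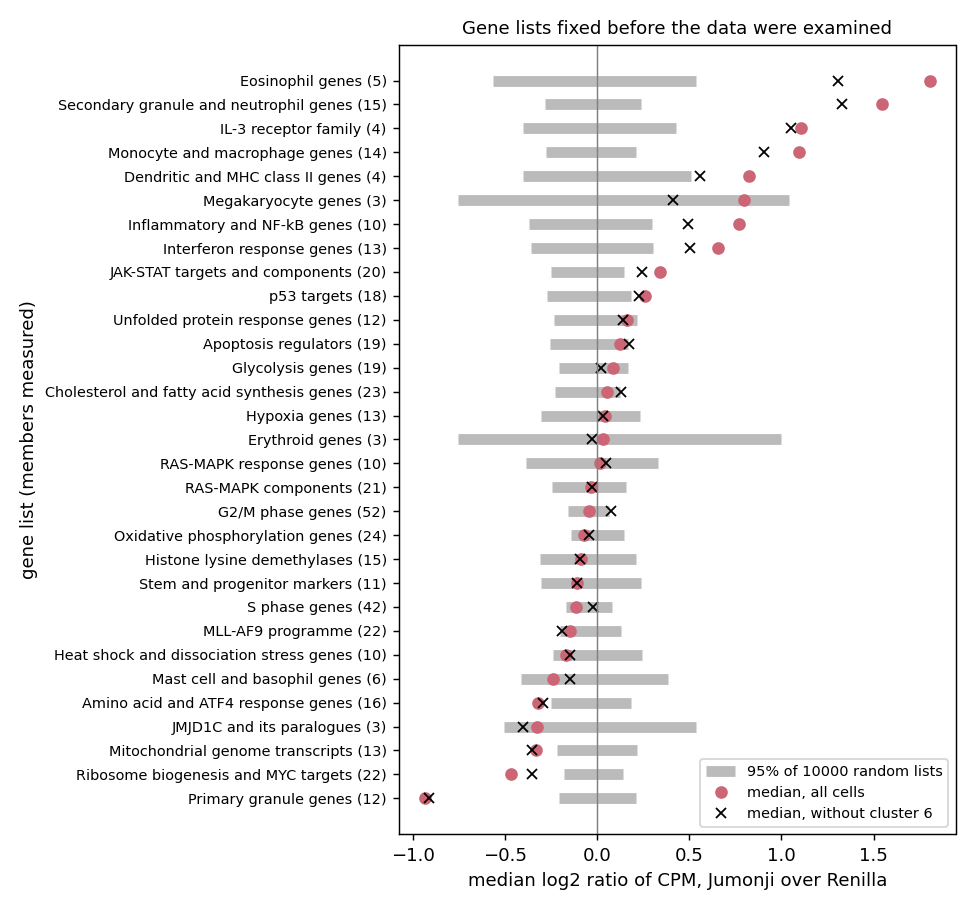
Median log2 ratio of CPM, Jumonji over Renilla, for each gene list with at least 3 measured members, for all cells (circles) and without cluster 6 (crosses), with grey bars for the central 95% of 10000 matched random lists. The bars were drawn from the ratios over all cells only, so they are no random range for the crosses. The neutrophil, monocyte and IL-3 receptor lists lie right of these bars in both settings. The primary granule list, at -0.93, lies farthest to the left.

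Clusters built without the genes that differ between the libraries were still filled unequally. Cluster 6 held 18 of 608 Renilla cells, or 2.96% (1.76% to 4.64%), and 118 of 575 Jumonji cells, or 20.5% (17.3% to 24.1%). Its cells were shallower than the rest, with a median of 12695 UMIs. Clusters 1 and 7 held 35.2% and 16.8% of Renilla cells against 4.52% and 1.91% of Jumonji cells, and cluster 5 held 2.47% against 21.0%. With 1 library per condition, clusters 1, 5, 6 and 7 may each be a library rather than a type of cell. Cluster 2 held 17.8% of Renilla and 21.2% of Jumonji cells, cluster 3 held 18.1% and 12.7%, and cluster 4 held 6.74% and 18.1%. Without cluster 6, which was left out as an alternative added after the clusters had been seen, 350 of the 417 higher and 95 of the 133 lower genes kept their 2-fold difference.

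More cells of the Jumonji library were called in G1. At 10000 UMIs per cell, G1 calls made up 26.0% (22.2% to 29.96%) of 520 Jumonji cells and 9.84% (7.54% to 12.6%) of 579 Renilla cells. Unthinned, the shares were 29.2% and 9.21%. Under the stricter cell filter they were 31.2% and 17.1% with cells thinned anew, and 22.9% and 8.82% on the same thinning draw. Of the cells of cluster 6, 78 of 118 Jumonji and 16 of 18 Renilla cells reached 10000 UMIs, so the thinned shares leave out many of its Jumonji cells. Among those kept, 75 of 78 Jumonji and 16 of 16 Renilla cells were called G1. Outside cluster 6 the shares were 13.6% (10.5% to 17.1%) and 7.28% (5.28% to 9.75%). Scores lay near the line between phases in 66 Jumonji cells (12.7%) and 66 Renilla cells (11.4%). The list medians were -0.12 for 42 S phase genes (percentile 13.5) and -0.04 for 52 G2/M genes (percentile 52.1), where the log2 ratio of summed CPM was 0.06. Neither has a stable direction, since the S phase median was 0.08 as a mean over clusters and the G2/M median 0.08 without cluster 6. The calls alone do not show how fast the cells divided. Free RNA in the droplets also enters such scores and was not measured.

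**Figure D3:**
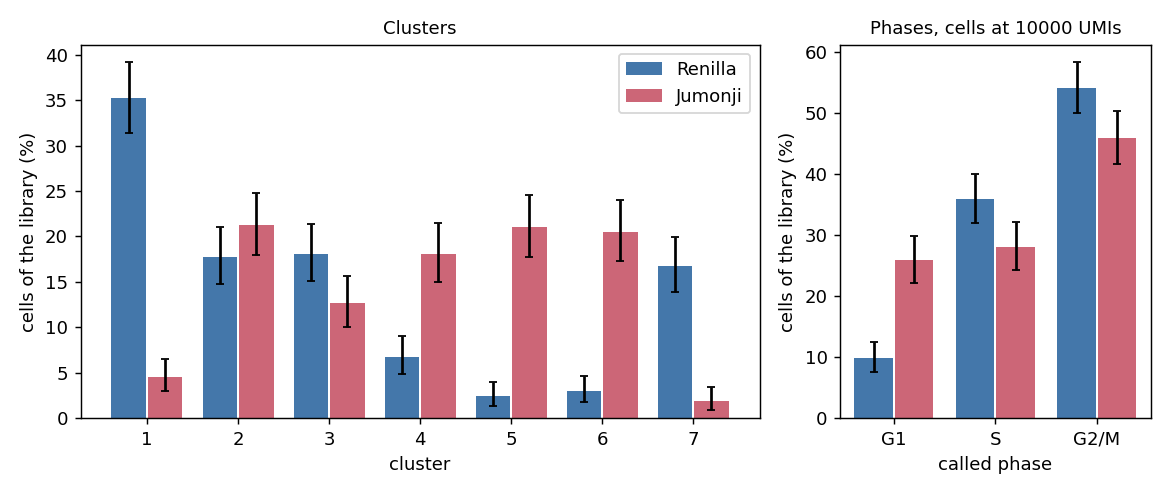
Share of each library's cells (%) in the 7 clusters (left) and in each called phase at 10000 UMIs per cell (right), Renilla in blue and Jumonji in red, with exact 95% binomial intervals. Cluster 6 holds 2.96% of Renilla and 20.5% of Jumonji cells, and G1 calls 9.84% and 26.0%.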

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

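The tests of library preparation and of shared barcodes were chosen after the results they bear on had been seen.

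Barcodes above 10% mitochondrial UMIs made up 11.8% (9.43% to 14.5%) of the Jumonji library and 6.61% (4.82% to 8.79%) of the Renilla library. They entered no main result, only the alternative with all deposited barcodes and the values given here. They drew attention because their share was above that of the control. Mpo was higher in the excluded barcodes than in the kept cells of both libraries, at 4660 against 607 CPM in the Renilla library and 434 against 68.4 CPM in the Jumonji library. Ctsg was higher too, at 2316 against 560 CPM (Renilla) and 538 against 87.0 CPM (Jumonji). Elane was lower in the excluded Jumonji barcodes, at 593 CPM (521 to 671) against 730, and Prtn3 in the excluded Renilla barcodes, at 1429 CPM (1286 to 1585) against 1721. The kept values of Elane in the Renilla library and of Prtn3 in the Jumonji library lay within the excluded intervals, 1511 to 1834 and 635 to 799 CPM. Jmjd1c was at 210 CPM (157 to 274) in the excluded Renilla and 322 CPM (271 to 381) in the excluded Jumonji barcodes, so the lower level in the Jumonji library was not seen there. Malat1, a nuclear RNA, was at 8805 against 3375 CPM (Renilla) and 10237 against 3589 CPM (Jumonji). The genes given for these barcodes were chosen after the clusters had been seen, and Malat1 lies outside the naming rule. In excluded Renilla barcodes S100a8 was at 475 CPM (64.3 in kept cells). In excluded Jumonji barcodes Wfdc17 was at 1079 CPM (281 in kept cells), while S100a8 was at 7.11 CPM, from 3 UMIs (498 in kept cells).

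The 2-fold differences between the libraries, 417 genes higher and 133 lower, were weighed against depth and against the pairing of the libraries. With every cell thinned to the same number of UMIs, 99.1% of these genes kept at least a 1.5-fold difference in the same direction. CPM is already scaled to the library total, and random thinning keeps each cell's expected gene shares. Little else could come out, so this value cannot decide on depth. Library preparation and culture cannot be told apart from the guide, since each condition has 1 library. An effect of the Jumonji guide stays open for the same reason, and so do effects of the guide outside its target.

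The genes higher in the Jumonji library were weighed against a larger share of cluster 6 cells. Without cluster 6 their median log2 ratio was still 1.39 (quartiles 1.09 and 2.04), so the share of cluster 6 as drawn is not enough. Its edge depends on the settings, and genes 1.5-fold apart were left out in drawing it. At resolution 0.3 the cluster holding all its cells took 37.7% of Jumonji and 9.38% of Renilla cells. Similar cells may thus remain among the others, and a larger share of such cells stays open. Free RNA from cluster 6 in the droplets of other cells would leave a like, small part of the cluster 6 level in them. The excess in the other Jumonji cells was instead 29.95% of the cluster 6 level at the median (quartiles 19.8% and 42.7%), and 37 of the 417 genes were at least as high outside cluster 6 as in it. Some contribution of free RNA to single genes stays open, as does a shift in the state of most cells, which may be biological but was found and tested on the same pair of libraries.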

How the results depend on the processing

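Leaving out cluster 6, the filters on the same thinning draw and another thinning draw were added after the data had been seen. All other alternatives were planned. Jmjd1c was lower in the Jumonji library under all 8 alternatives (-0.40 to -0.25). In the excluded barcodes alone it was not lower (322 CPM against 210 CPM). Of the 13 lists whose median lay outside the central 95% of random lists, all 143 alternative medians kept their sign, but 9 of the 13 moved by more than 1.5 times under at least 1 alternative. Of the other 18 lists, 11 changed sign under at least 1 alternative, so no direction is established for those 11 (RAS-MAPK response and components, stem and progenitor, mast cell, erythroid, megakaryocyte, S phase, G2/M, glycolysis, cholesterol and fatty acid, and demethylase lists). Lists that kept their sign moved too. Median ratio scaling gave -0.09 for the MLL-AF9 programme and -0.01 for oxidative phosphorylation, and thinned cells gave 0.20 for hypoxia genes. At a minimum of 30 UMIs 644 genes were higher and 283 lower by 2-fold, at 300 UMIs 254 and 59, because more or fewer genes were counted, and the mean of per-cell CPM gave 200 lower genes. That mean moved the IL-3 receptor median to 1.22, the neutrophil median to 1.97 and the monocyte median to 1.31. A mean over clusters gave 0.91, 1.04 and 0.59 for these lists and -0.57 for primary granule genes. Without cluster 6 the neutrophil median was 1.33 and the monocyte median 0.90. A minimum of 1 UMI gave 1.71 and 0.90, a minimum of 200 UMIs gave 1.75 for neutrophil genes, and thinned cells gave 1.27 for monocyte genes. The cluster holding the cells of cluster 6 took 9.38% of Renilla and 37.7% of Jumonji cells at resolution 0.3, and 36.2% of Jumonji cells with all variable genes. G1 calls were more frequent in the Jumonji library in every setting tried. The stricter cell filter, thinned anew, gave G1 shares of 17.1% (Renilla) and 31.2% (Jumonji) and G2/M shares of 48.0% and 40.6%. Unthinned cells gave S shares of 44.6% and 33.0% and G2/M shares of 46.2% and 37.7%. Without doublets and thinned anew, the S shares were 43.4% and 35.9% and the G2/M shares 48.0% and 39.3%. On the first draw the stricter filter gave S shares of 41.3% and 34.2% and a Renilla G2/M share of 49.9%, while leaving out doublets moved no share beyond its interval. Another draw of the same cells gave a Renilla G2/M share of 49.7%, so part of the movement between S and G2/M comes with the draw and the rescoring, and is not shown to come from doublets. The median depth of the Jumonji library was 20451.5 UMIs over all barcodes. Except where the count minimum is named, the cause was not tested. Members under 50 UMIs entered no list median, and whether depth or lack of expression kept them there was not tested.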

Other observations

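The count of barcodes shared between the libraries and the reference values of the correlation below were chosen after the results had been seen.

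Inflammatory and interferon lists had higher medians in the Jumonji library, over the members measured. Of 21 inflammatory genes listed, Il1b, Il1a, Cxcl2, Cxcl10, Ccl2 and Tnfaip3 were among those not measured. Of 26 interferon genes listed, Ifit1, Ifit2, Ifit3, Oasl2, Rsad2, Mx1 and Usp18 were among those not measured. Such genes were below the count minimum or had no identifier, and the medians leave them out. Of 10 measured inflammatory and NF-kB genes, 7 were at least 1.5-fold higher and none lower (median 0.77, above all random lists). This median was 2.05 in thinned cells, 1.74 at a minimum of 200 UMIs, 0.49 without cluster 6 and 0.40 as a mean over clusters. Its members included Ccl6 at 4.10 (3.64 to 4.60), Il1rn at 3.42 (2.82 to 4.10) and Ccl3 at 2.5 (2.10 to 2.92). Of 13 measured interferon response genes, 7 were higher and none lower (median 0.65, percentile 99.95, or 0.33 as a mean over clusters), among them Zbp1 at 3.82 (2.72 to 5.18) and Ifi27l2a at 2.40 (1.89 to 2.96), or 1.73 without cluster 6, while Isg15 was at -0.39 (-1.19 to 0.38). Among 18 p53 targets 6 were higher (median 0.26, percentile 99.4, or 0.16 as a mean over clusters), with Perp at 2.81 (1.78 to 4.01), Trp53inp1 at 2.03 (1.40 to 2.70) and Fas at 1.51 (1.12 to 1.90). Of 19 apoptosis regulators 4 were higher (median 0.13, percentile 94.9, or 0.04 at a minimum of 200 UMIs). The anti-apoptotic Bcl2a1a was at 3.0 (2.63 to 3.39) and Bcl2a1b at 2.71 (2.49 to 2.93), copies so similar that their split is uncertain.

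Several growth-related lists had lower medians, with most members within 1.5-fold. The 22 ribosome biogenesis and MYC target genes had a median of -0.47, below all random lists, with 5 at least 1.5-fold lower, 17 within 1.5-fold and none higher. The median was -0.35 without cluster 6 and -0.13 as a mean over clusters. Polr1b at -1.30 (-1.70 to -0.91) and Cad at -1.0 (-1.25 to -0.77) were lowest. The 13 mitochondrial genome transcripts had a median of -0.33 (percentile 0.13), though barcodes were selected on their summed share. The 16 amino acid and ATF4 response genes had a median of -0.32 (percentile 0.39, or -0.14 as a mean over clusters), of which 12 lay within 1.5-fold, with Phgdh at -0.76 (-0.85 to -0.68) and Nupr1 at 0.76 (0.61 to 0.91). Other metabolic and stress lists lay inside the central range of random lists, with medians of 0.09 for glycolysis (percentile 89.7), 0.05 for cholesterol and fatty acid synthesis (89.0), 0.17 for the unfolded protein response (94.4), -0.17 for heat shock (9.03) and -0.07 for oxidative phosphorylation (18.1). The 13 hypoxia genes had a median of 0.04 (percentile 76.7), but their summed CPM had a log2 ratio of -0.53, with Mif at 530 of 970 CPM in the Jumonji and 1020 of 1398 CPM in the Renilla library. Median and summed CPM also differed in sign for the RAS-MAPK response (summed -0.06), cholesterol and fatty acid synthesis (-0.01) and erythroid (-0.27) lists.

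A hypothesis was that the difference between the libraries runs along a difference that already exists among control cells. Across 8959 genes, the log2 ratio between libraries without cluster 6 and the log2 ratio of cluster 6 over other cells within the Renilla library had a Pearson correlation of 0.411 (Spearman 0.38), with separate sets of Renilla cells on each side. Over 100 draws with Renilla cells in place of the Jumonji library it was 0.0023 at the median and 0.132 at most. Without a library difference a value near 0 had to come out. These draws check only whether the computation itself makes a correlation. They do not show what a library difference of another origin would give. With depth-matched Renilla cells in place of cluster 6 it was -0.0884 at the median, which argues against depth. Cluster 6 was built from both libraries, and a group of 144 cells found in the Renilla library alone, holding 17 of the 18 cells, gave 0.341 (0.298 to 0.369 over 100 draws). The values go with the hypothesis but are no independent test of it. The 18 cells were picked by grouping with Jumonji cells, and the group of 144 overlaps them. Genes are not independent replicates, and other explanations stay open.

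With all variable genes used for clustering, 31 of 608 Renilla cells (5.10%, 3.49% to 7.16%) grouped with Jumonji cells, 16 of them from cluster 6, and 11 of 575 Jumonji cells (1.91%, 0.959% to 3.40%) grouped with Renilla cells. None was called a doublet. Reads moved between libraries under the same barcode would need barcodes present in both, and 0 were shared.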
